A study of Mus musculus with 6 samples.

How the data were processed

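RNA was taken from heart ventricles of E12.5 mouse embryos, in 3 control and 3 LSD1 conditional knockout samples, with groups and replicate numbers taken from the sample descriptions. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra RNA kit, which does not mark strand. The submitters' processing notes name CASAVA, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 genome. Their order, the annotation release and the counting options are not given in the sources used here. The authors deposited FPKM values, fragments scaled by gene length and by a library total, in 1 table of 54532 Ensembl gene IDs and 6 libraries, with no read counts.

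Gene names, exon lengths and coordinates were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, by Ensembl ID. It held 54409 of the IDs, and 123 had no match and kept no name. Where several IDs shared a symbol, the ID with the highest mean kept it, a rule set after 1 list was seen to hold an extra ID. FPKM multiplied by exon length gave whole multiples of 1 step per library. Between 98.1% and 98.5% of genes under 30 reads lay within 0.02 of a whole read. The recovered reads summed to 17896744 to 20073994 per library. The total that sets the FPKM step was 0.943 to 1.005 of the summed reads, but divided by the library's median-of-ratios size factor it was the same in the 6 libraries to 3 digits, so the deposited FPKM were scaled by size factors rather than by summed reads. A gene of 1 kb with 3 reads, the floor used here, stands at 0.155 to 0.169 FPKM.

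Genes with a mean of at least 0.5 FPKM over the 6 libraries (14149) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided, genotype as the only term, and Benjamini-Hochberg adjusted p under 0.05. Fold changes on that scale understate the change of low genes, so ratios of mean FPKM are given beside them. Kdm1a and Cend1 were also compared by an exact permutation test, two-sided. The 34 gene lists were fixed before the data were examined, and 32 had at least 5 tested members. These were compared with other genes by camera (preset correlation 0.01), adjusted over the 32 lists, and again with an estimated correlation. They were also tested by fry, which asks whether the genes of a list change and does not compare them with other genes. The count "adjusted over the list alone" uses the p-values of the list's members only. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

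The lists covered LSD1 and CoREST complex partners, H3K4 methyltransferases and demethylases, neuronal genes, neural crest and cardiac ganglion markers, both cell cycle phase lists, cell cycle inhibitors, p53 targets, cardiac transcription factors, second heart field genes, sarcomere genes, calcium handling, ion channels, ventricular wall signalling, TGF-beta and BMP, Wnt, endothelial, cushion, epicardial, smooth muscle, atrial, erythroid, immune, liver and lung, skeletal muscle, germline, Hox, nuclear and mitochondrially encoded respiratory genes, glycolysis, hypoxia, fatty acid oxidation, immediate early and sex-linked genes. The Ahsp symbol of the erythroid list was not matched. Genes were named by a rule fixed before the data were examined: Kdm1a and Cend1, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, up to 4 called members of each list or else the 2 with the smallest p, and the 5 remaining genes with the smallest adjusted p. Predicted gene models, pseudogenes and the genes of the sex-linked list (Xist and Y-linked genes) were left out of the largest changes; other X-linked genes were not. Not every gene that the rule takes is reported here.

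Libraries were compared for copies of each other by a chi-square per gene on recovered reads. The median lay at 1.92 or above for every pair, against 0.455 for sampling noise alone, so each library counted as 1 replicate. Pearson correlations across genes were 0.987 to 0.991 within control, 0.989 to 0.990 within knockout and 0.983 to 0.986 between groups; genes are not independent replicates. Strand was not recorded in the library, so reads of overlapping antisense genes cannot be told apart. The share of each named gene's exon bases that lie under another gene's exons was computed for this reason and is given where it is above 10%.

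The procedure was tested on simulated data in 5 runs, each with 200 of the 14149 genes changed and a biological coefficient of variation of 7.55%. It called 63% of genes changed 1.5-fold, 94% of those changed 2-fold and 99.4% of those changed 4-fold, with 14.2 unchanged genes called per run. A list of 40 genes raised 1.3-fold was called in 5 of 5 runs, and 0 of 160 unchanged lists were called. The simulated genes varied independently and all shared that 1 coefficient of variation, unlike those of real libraries. The shares called need not hold for genes that vary more.

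Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, other filters on low values, rescaling to TPM, by median of ratios, by quantiles or without haemoglobin and mitochondrial genes, robust and untrended limma fits, library weights, the replicate number as a block, haemoglobin and sex covariates, stricter thresholds and leaving out each library. A limma voom fit on the recovered reads and a fit of autosomal genes were added after seeing the data. Lists of interferon-stimulated genes, epithelial genes and abundant neuronal transcripts, used in the closing observations, were written after the called genes were seen.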

Results

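Gene expression was measured by RNA sequencing in heart ventricles of E12.5 mouse embryos. There were 3 control libraries and 3 libraries from a conditional knockout of Kdm1a, the gene for the histone demethylase LSD1, which acts with the CoREST repressor complex. The labels do not state where the gene was deleted, nor whether the samples of a group came from separate embryos or litters. The p-values therefore measure the spread between these samples, which may be technical in part. The sex-linked RNA of knockout replicate 3, described below, shows that it came from other embryos than the rest. For the remaining libraries this stays unknown. The series title names Cend1 as a gene repressed by LSD1, and the comparison asks which transcripts differed between the knockout and control ventricles. The deposited values are FPKM for 54532 genes, of which 25956 were above 0 in at least 1 library. Whole reads recovered from the FPKM steps summed to between 17896744 and 20073994 per library, and 1 read in a gene of 1 kb was worth between 0.0515 and 0.0562 FPKM. Counting intervals and floors cover counting error only.

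Kdm1a itself was lower in the knockout. Its level was 27.5 ± 4.08 FPKM (SD, n = 3) in control and 11.1 ± 0.555 FPKM (SD, n = 3) in knockout ventricles, a ratio of 0.405, and each knockout library lay below each control library (log2 change -1.22, SE 0.11, limma adjusted p = 0.00274). The gene lies on chromosome 4 from 136550540 to 136602723 on the minus strand of mm10. A gene total includes exons outside a deleted part and RNA of cells that were not targeted, so the remaining level does not give the share of intact transcript. Cend1, which encodes a protein of neuronal cell cycle exit and differentiation, was higher. It rose from 9.18 ± 1.63 FPKM (SD, n = 3) to 29.7 ± 2.5 FPKM (SD, n = 3), a ratio of 3.23 (log2 change 1.60, SE 0.12, limma adjusted p = 0.00159). Cend1 lies on chromosome 7 from 141426446 to 141429491 on the minus strand, with no exon overlap with another gene. A two-sided exact permutation test of the group means gave p = 0.1 for each of the 2 genes, the smallest p that 3 against 3 libraries allow. The study may have chosen Cend1 from these same samples, so its direction here is not independent evidence.

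Most genes that changed were higher in the knockout. Among 14149 genes with a mean of at least 0.5 FPKM, 270 rose and 66 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 2274 had an unadjusted p under 0.05. Of the called genes, 129 were at least 2-fold higher by mean FPKM and 15 at least 2-fold lower. The genes that rose had lower control levels, with a median of 2.84 FPKM against 11 FPKM for those that fell. A control mean under 5 FPKM was found for 63.3% of the higher and 33.3% of the lower genes, against 47.8% of the genes tested. All 336 called genes had knockout libraries outside the control range, as did 21.4% of the genes tested, where chance gives 10%. The counts changed with the library left out. Without control replicate 1 there were 146 higher and 28 lower genes, without control replicate 2 there were 156 and 28, and without control replicate 3 there were 281 and 113. Leaving out a knockout library gave 138 and 24 (replicate 1), 109 and 23 (replicate 2) or 123 and 27 (replicate 3). In all 6 of these fits 108 of the 336 genes stayed called. No Kdm1a or Cend1 call was lost.

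**Figure D1:**
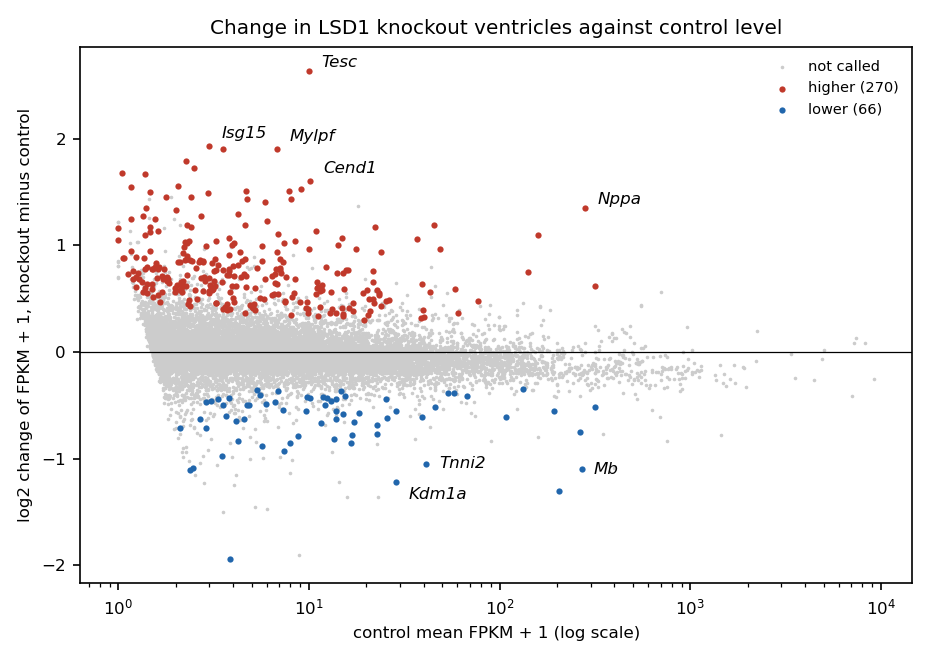
Change of each tested gene, as log2(FPKM + 1) in knockout minus control (vertical axis), against its control mean FPKM + 1 (horizontal log axis), 3 libraries per group. Red points are the 270 higher genes and blue points the 66 lower genes, predicted gene models included, and grey points did not pass the test; most red points lie at low control levels, and Xist is not drawn.

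The libraries differed in sex as well as genotype. Knockout replicate 3 had 12.1 FPKM of Xist, the RNA of the inactive X chromosome (12.6% of its exon bases lie under Tsix and other genes), and 0 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The other 5 libraries had reads of all 4 Y-linked genes, with Ddx3y between 13.1 and 14.3 FPKM. Knockout replicate 1 had these and also 1.11 FPKM of Xist (360 reads), whereas the remaining 4 libraries had at most 4 Xist reads. With a sex score (Xist minus the mean Y-linked log2 level) as covariate, 93 genes were higher and 23 lower. That score mostly sets knockout replicate 3 apart, so the fit cannot tell sex from other traits of that library. Leaving out any knockout library lowered the counts as well, as given above. Control replicate 3 had the highest share of mitochondrially encoded transcripts (9.03% of its FPKM sum, against 4.64% to 7.1% in the other 5) and the highest haemoglobin share, 4.32%, against 1.98% to 4.31%. The first principal component, 36.3% of the variance, separated the genotypes, and the second, 22%, set control replicate 3 (-20.7) apart from the others (-5.7 to 11).

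The largest rises were in genes of varied function. Tesc, which encodes the calcium-binding protein tescalcin, rose from 9.01 ± 1.37 to 60.8 ± 7.07 FPKM (SD, n = 3 each), a ratio of 6.74 and a log2 change of 2.63 (SE 0.12, limma adjusted p = 0.000476). Syngr3, a synaptic vesicle protein gene, went from 0.0435 ± 0.0152 FPKM, below the 3-read floor in 1 kb of 0.155 to 0.169 FPKM, to 2.4 ± 0.831 FPKM. Isg15, an interferon-induced ubiquitin-like protein gene, rose 5.57-fold. The X-linked gene Tceal6 rose 5.43-fold, Stac2 4.83-fold, Cldn3 4.67-fold and Guca1a, a guanylate cyclase activator of photoreceptors, 4.65-fold. Tmem35a, also X-linked, rose 3.08-fold and the metallothionein gene Mt3 3.14-fold. Among the smallest adjusted p-values were also Nrsn2 (3.97-fold, with 16.6% of its exon bases under Gm14164), C1qtnf4 (2.17-fold), Akr1b8 (2.31-fold), the meiotic gene Meioc (4.97-fold) and Stx11 (2.82-fold). In this group only Isg15 lost its call when a single library was left out, and it stayed called in 3 of those 6 fits.

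The largest falls, after Kdm1a, were likewise in genes of varied function. Mb, which encodes myoglobin, fell from 268 ± 6.89 to 125 ± 3.37 FPKM (SD, n = 3 each), a ratio of 0.466 (log2 change -1.10, SE 0.06, limma adjusted p = 0.000566), although 31.9% of its exon bases overlap Apol6 or Gm49540. Depp1 fell to 0.451 of the control level, the elastic fibre gene Fbln5 to 0.494, Psd to 0.421, and the neuropeptide gene Nts to 0.523. Cldn5, a tight junction gene of endothelium, fell to 0.531 and the insulin-like growth factor binding protein gene Igfbp3 to 0.567. Of these 7 genes, Fbln5 was called in 0 and Psd in 1 of the 6 fits that left out a library, and the other 5 in each.

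Neuronal genes were among those that rose. Of 60 listed neuronal genes, 19 were expressed highly enough to be tested, 5 rose and 0 fell, both over all genes and adjusted over the list alone. Gng3, a G protein gamma subunit, rose from 0.386 ± 0.277 to 3.4 ± 0.636 FPKM, the axonal transport motor Kif1a from 1.68 ± 0.191 to 3.89 ± 0.431, Scg5 from 0.241 ± 0.0298 to 1.31 ± 0.229 and Syt11 from 3.68 ± 0.366 to 6.13 ± 0.365 (SD, n = 3 each). The fifth was Uchl1, outside the rule for named genes and chosen after its values were seen, at 76 ± 5.33 and 106 ± 1.25 FPKM. Exons of other genes cover 24.2% of Gng3 and 18.1% of Uchl1. The list median was 0.04 and its mean 0.21 on the log2 scale. The list as a whole missed the threshold by camera (adjusted p = 0.054, and adjusted p = 0.786 with an estimated correlation). Fry, which asks whether the list moves on balance in one direction without comparing it with other genes, gave an adjusted p of 0.0116. Without knockout replicate 2, without knockout replicate 3 or with the sex score as covariate, 3 neuronal genes were called. The camera adjusted p was 0.0407 without control replicate 1 and 0.0261 without knockout replicate 3. It was 0.14 without the filter on low values and 0.145 at a mean of at least 5 FPKM. Neural crest and cardiac ganglion markers had 0 of 10 members called either way, also adjusted over the list alone (camera adjusted p = 0.104). That list passed on the higher side without control replicate 3 (adjusted p = 0.0227) and without knockout replicate 3 (0.0316). It also passed with library weights (0.0488) and with the sex score as covariate (0.0366). All of these fits kept knockout replicate 1, and without that library the camera adjusted p was 0.356. The list's mean log2 level was 2.42 in knockout replicate 1. It was 1.94 and 1.92 in the other knockout libraries and 1.73 to 1.97 in the controls. Ednrb was at 31.6 ± 9.02 and 40.5 ± 3.15 FPKM and Gata2 at 3.07 ± 0.393 and 3.65 ± 0.462 (SD, n = 3 each). In knockout replicate 1 the crest gene Sox10, chosen after its values were seen, stood at 5.24 FPKM, against at most 0.61 in the other 5 libraries.

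**Figure D2:**
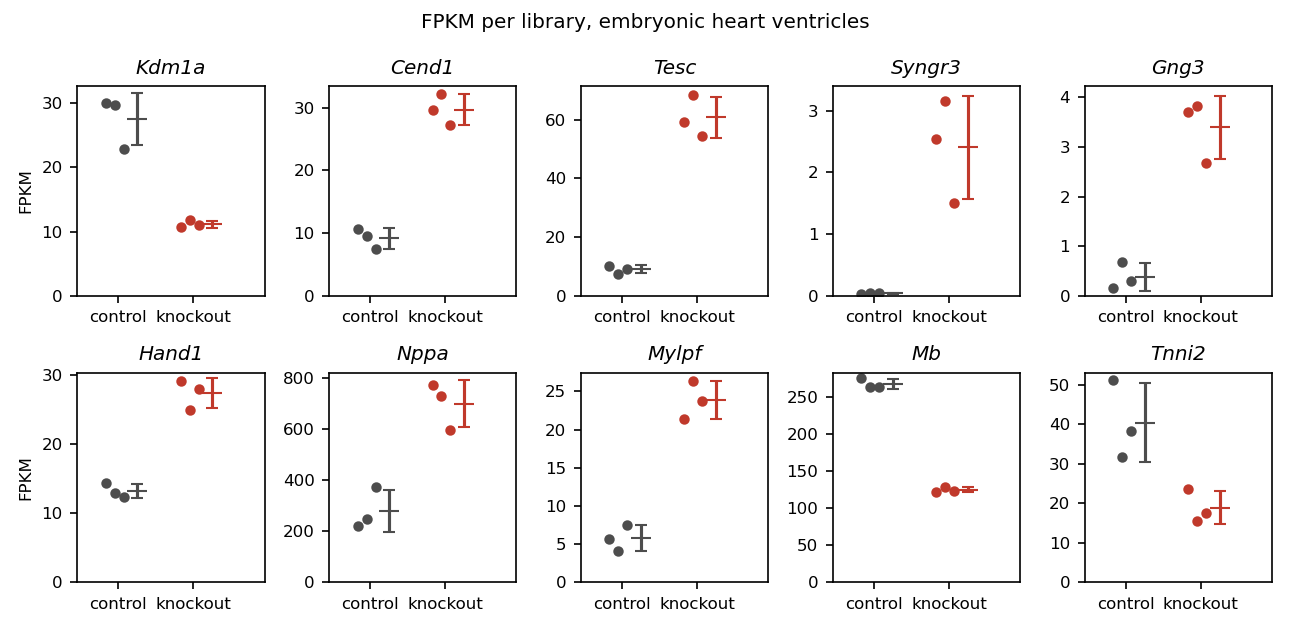
FPKM of 10 genes in each of the 3 control (grey) and 3 knockout (red) libraries; points are libraries, and the bar beside them gives the mean and SD. Each vertical axis starts at 0 and differs between genes; in each panel the 3 knockout libraries lie wholly above or wholly below the 3 control libraries.

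Patterning and wall genes of the ventricle rose in part. Of 35 cardiac transcription factors tested, 3 rose and 0 fell, and the same numbers passed adjusted over the list alone. Hand1, a factor of the left ventricle, rose from 13.2 ± 1.04 to 27.3 ± 2.16 FPKM, a ratio of 2.07 (SD, n = 3 each), and the Iroquois factors Irx6 and Irx5 rose 1.92-fold and 1.64-fold. Among 39 trabecular and ventricular wall signalling genes 3 rose and 0 fell, and adjusted over the list alone 3 rose and 1 fell. The natriuretic peptide gene Nppa went from 281 ± 82.5 to 700 ± 91.8 FPKM and Nppb from 158 ± 45.2 to 332 ± 48.7 FPKM, and the coregulator gene Cited1 rose 1.68-fold (SD, n = 3 each). Exons of Gm13054 cover 61.5% of Nppa. Hand1 and Cited1 stayed called in each fit that left out a library. Nppa and Nppb stayed called in 2 of 6 fits, Irx6 in 4 and Irx5 in 1. Of the transcription factors 1 was called without knockout replicate 2, without knockout replicate 3 or with the sex score as covariate. Neither list passed the camera test with all 6 libraries (adjusted p = 0.252 and 0.108), while the wall signalling list passed on the higher side without control replicate 3 (adjusted p = 0.00526) and with library weights (0.0243). Of 13 second heart field and outflow tract genes, Foxc1 rose (1.45-fold) and 0 fell, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.724). Atrial markers had 0 of 14 called, with the same result adjusted over the list alone (camera adjusted p = 0.298); Nr2f2 was at 3.38 ± 0.189 and 4.41 ± 0.306 FPKM, and Sln at 7.67 ± 1.57 and 5.42 ± 0.716 (SD, n = 3 each).

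Contractile genes typed as skeletal changed in both directions, while most cardiac sarcomere genes did not pass the test. Mylpf, the fast skeletal regulatory light chain, rose from 5.77 ± 1.69 to 23.8 ± 2.47 FPKM and Myl1, a skeletal essential light chain, from 36 ± 2.2 to 76.2 ± 4.71. Tnni2, fast skeletal troponin I, fell from 40.3 ± 9.96 to 18.9 ± 4.17 FPKM and Tnnt1, slow skeletal troponin T, from 264 ± 41.6 to 155 ± 8.98 (SD, n = 3 each). These 4 were the called members among 9 tested skeletal muscle genes, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.226). Whether reads of Mylpf or Myl1 were divided with the annotated pseudogene Mylf-ps was not measured. Tnni2 and Tnnt1 each stayed called in 2 of the 6 fits that left out a library, Mylpf and Myl1 in all 6. Of 41 sarcomere and Z-disc genes 0 rose and 1 fell, with the same counts adjusted over the list alone: Fhl2 went from 131 ± 2.8 to 103 ± 2.21 FPKM (SD, n = 3 each). The count turned to 1 higher and 0 lower after rescaling to TPM, by quantiles or without haemoglobin and mitochondrial genes, where the call was Smpx, named here after its values were seen; without control replicate 3 it was 0 and 4. That list had camera adjusted p = 0.273, and 0.00137, on the lower side, without control replicate 3. Of 27 calcium handling genes 1 rose, and adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 0.114, and 0.0242, on the higher side, without knockout replicate 1). After rescaling to TPM or by quantiles 2 rose and without haemoglobin and mitochondrial genes 3. The called gene was Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 1.74-fold. Ion channel and gap junction genes moved both ways, with 3 of 26 higher and 2 lower, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.465). Kcnj3 rose 1.96-fold (31.1% of its exon bases lie under Gm26794), while Kcnj8 fell to 0.549 and the T-type calcium channel gene Cacna1h to 0.631 of control.

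Cell cycle genes did not pass the test as single genes. None of 46 genes of the G1 and S phases and none of 46 genes of the G2 and M phases was called by limma, either over all genes or adjusted over the list alone. The list medians were -0.06 and -0.08 on the log2 scale (camera adjusted p = 0.226 and 0.104). Control replicate 3 had a mean level of the G2 and M list of 4.2, against 4.47 and 4.48 in the other controls. Without it the camera adjusted p-values at the preset correlation were 0.00441 and 2.11e-07, on the lower side. The correlation estimated from all 6 libraries was 0.282 for the G1 and S list and 0.595 for the G2 and M list. With these estimates camera gave both lists an adjusted p of 0.883. Without knockout replicate 1 the G2 and M list had a camera adjusted p of 0.0242. Rescaling without haemoglobin and mitochondrial genes gave 1 call, Ccnd2, on the higher side. Ccnd2 was at 43 ± 1.94 and 53.1 ± 3.63 FPKM, Ccnd1 (23.4% of its exon bases lie under LTO1) at 27.6 ± 1.53 and 31.2 ± 1.02, Ttk at 7.19 ± 0.187 and 5.85 ± 0.329 and Cenpe at 4.16 ± 0.272 and 4.81 ± 0.183 (SD, n = 3 each). Of 25 cell cycle inhibitors and exit genes, Gadd45g fell, to 0.725 of control, and 0 rose; adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.841). After rescaling to TPM that count was 1 higher and 0 lower, the call being Cdkn1a, named here after its values were seen. Of 30 p53 targets and apoptosis genes 2 rose and 0 fell, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.134). These were Pmaip1, a pro-apoptotic gene, from 1.77 ± 0.232 to 3.96 ± 0.365 FPKM, and Perp, from 57.5 ± 6.81 to 86.9 ± 1.25 FPKM (SD, n = 3 each).

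The lists of nuclear oxidative phosphorylation, glycolysis and fatty acid oxidation genes were lower as groups by the camera test at its preset correlation, with few single calls, while the hypoxia and mitochondrially encoded lists did not pass. With an estimated correlation none of these calls held (adjusted p = 0.786, 0.883 and 0.883). In mean log2(FPKM + 1) the oxidative phosphorylation list lay lower in each knockout library than in each control library. Control replicate 3 broke that order in the others: its glycolysis mean was 6.30, against 6.32 to 6.47 in the knockout libraries, and its fatty acid oxidation mean was 4.43, against 4.38 to 4.48. Without it both were still called lower (adjusted p = 1.57e-08 and 3.91e-05). Nuclear genes of oxidative phosphorylation had 0 of 58 called either way, also adjusted over the list alone, and a median log2 change of -0.20; 4 members had a fitted change above 0 (camera adjusted p = 7.41e-10, adjusted p = 0.786 with an estimated correlation). Cox6c was at 148 ± 15.5 and 115 ± 2.77 FPKM and Cox7a1 at 87.6 ± 5.42 and 120 ± 18.2 (SD, n = 3 each), the latter a single higher call after rescaling without haemoglobin and mitochondrial genes. Fatty acid oxidation genes had 0 of 29 called over all genes, 0 higher and 1 lower adjusted over the list alone, and a median of -0.13 (camera adjusted p = 0.00466, adjusted p = 0.883 with an estimated correlation, and 0.111 without control replicate 2). Acaa2 was at 191 ± 15.8 and 144 ± 8.54 FPKM and Decr1 at 23.7 ± 0.83 and 20 ± 0.39. Of 25 glycolysis genes 1 rose and 2 fell, and 1 rose and 6 fell adjusted over the list alone. The list median was -0.14 (camera adjusted p = 0.00766, adjusted p = 0.883 with an estimated correlation, 0.098 without control replicate 1, 0.114 without control replicate 2, 0.0628 at a mean of at least 5 FPKM and 0.187 after quantile normalization). Aldoc fell to 0.53 and Eno3, the muscle enolase, from 191 ± 12.8 to 130 ± 5.37 FPKM, while the glucose transporter gene Slc2a3 rose 1.71-fold. Among 27 hypoxia response genes Bnip3 fell, to 0.65 of control (22.3% of its exon bases lie under Gm45507), and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.114, and on the lower side 0.00449 without control replicate 3 and 0.0324 with library weights). After rescaling to TPM 0 were called. The 13 mitochondrially encoded genes, 0 called and 0 adjusted over the list alone, had a median of -0.24 (camera adjusted p = 0.132). The list passed on the lower side after rescaling to TPM (adjusted p = 0.0183), with the haemoglobin covariate (0.0105) and with the sex score (0.0191). It also passed without control replicate 2 (0.0453), knockout replicate 1 (0.0242) or knockout replicate 3 (0.0316). It did not pass without control replicate 3 (0.858) or with an estimated correlation (0.883). Its mean log2 level was 7.77 in knockout replicate 2. That mean was 8.43 and 8.52 in the other knockout libraries and 8.26 to 8.80 in the controls. Its members included mt-Nd1 at 7080 ± 1740 and 5340 ± 1320 FPKM and mt-Nd3 at 83.7 ± 17.1 and 65.8 ± 10.1 (SD, n = 3 each).

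**Figure D3:**
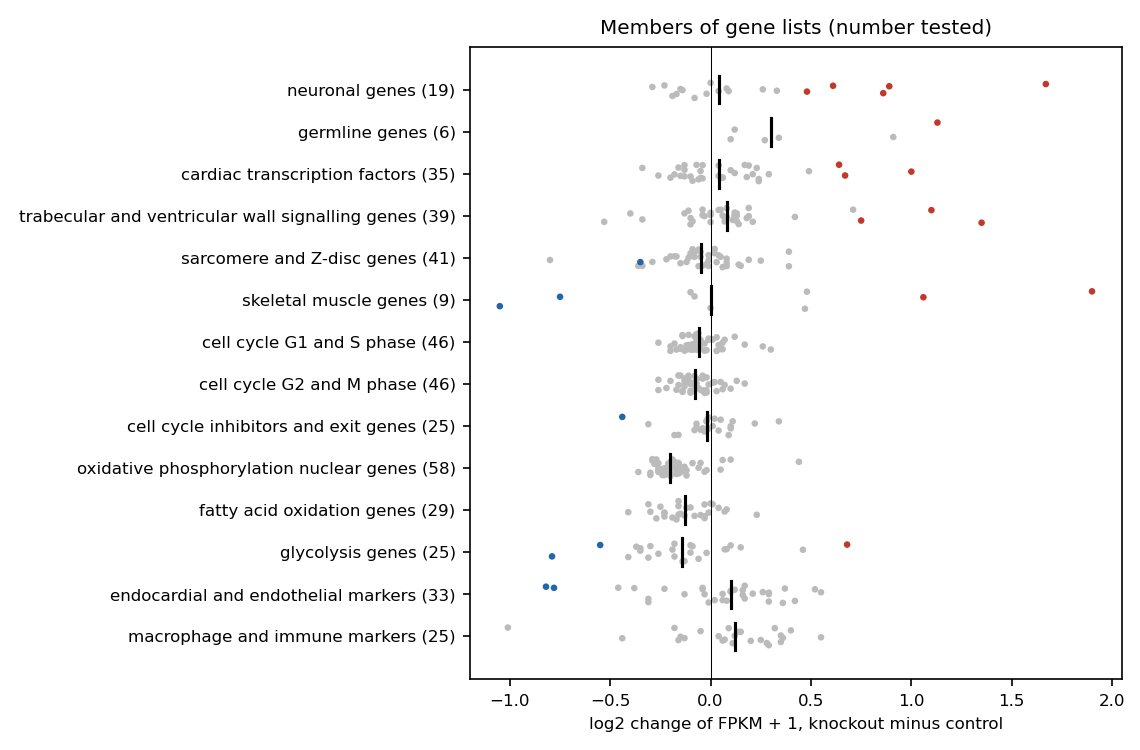
Log2 change of FPKM + 1, knockout minus control (horizontal axis), of the tested members of 14 gene lists; each point is a gene, the black bar the list median, red and blue points the genes that rose or fell and grey points those that did not pass. The nuclear oxidative phosphorylation genes sit mostly below 0 with a median of -0.20 and 0 called members, whereas the neuronal list has a median of 0.04 and 5 called members.

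Markers of other cell types gave few calls. Of 33 endocardial and endothelial markers 2 fell, Cldn5 and Fabp4 (to 0.561 of control), and 0 rose; 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.465, and 0.00258, on the higher side, without control replicate 3). Macrophage and immune markers had 0 of 25 called over all genes and 4 higher adjusted over the list alone, with a median of 0.12 (camera adjusted p = 0.00766, adjusted p = 0.843 with an estimated correlation, and 0.111 without control replicate 2). Ctss was at 14.6 ± 1.86 and 21.8 ± 2.98 FPKM and C1qc at 15.9 ± 0.217 and 19.1 ± 0.708 (SD, n = 3 each). After rescaling to TPM 2 immune markers rose, and without haemoglobin and mitochondrial genes 3. Of 17 epicardial markers Krt8 rose 1.74-fold and 0 fell, also adjusted over the list alone (camera adjusted p = 0.132, and on the higher side 0.0195 without control replicate 1 and 0.0299 without control replicate 3). Of 13 smooth muscle and pericyte genes Kcnj8 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.841). Cushion mesenchyme and fibroblast matrix genes had 0 of 38 called, also adjusted over the list alone (camera adjusted p = 0.747, and 0.0385, turned to the higher side, without control replicate 3). Rescaling to TPM gave 1 call, Eln, on the lower side. The elastin gene Eln was at 21.9 ± 7.6 and 7.95 ± 3.16 FPKM and Msx2 at 1.74 ± 0.46 and 2.83 ± 0.236. Erythroid markers had 0 of 23 called over all genes and 2 lower adjusted over the list alone (camera adjusted p = 0.902, and 0.0324, on the lower side, with the sex score as covariate), with Tfrc at 11.4 ± 1.83 and 7.28 ± 1.15 FPKM and Car2 at 19.6 ± 1.35 and 14.1 ± 2.26. Of 20 liver and lung markers 4 were tested, too few for a list test, and Epcam rose from 0.188 ± 0.174 to 1.01 ± 0.21 FPKM (SD, n = 3 each), the same single call adjusted over the list alone and no call after quantile normalization.

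Germline genes gave 1 call of 6 tested and 2 higher adjusted over the list alone. The meiotic recombinase gene Dmc1 rose from 0.617 ± 0.159 to 2.55 ± 0.49 FPKM (SD, n = 3 each). The list was called higher by camera (median 0.30, adjusted p = 0.00766, adjusted p = 0.786 with an estimated correlation), and no longer without knockout replicate 1 (adjusted p = 0.0994) or without the filter on low values (adjusted p = 0.055). Wnt pathway genes moved both ways, with Dkk3 (1.76-fold) and Tcf7 (1.46-fold) higher and Fzd1 lower (0.722 of control) among 33 tested, and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.465). After rescaling to TPM or without haemoglobin and mitochondrial genes the Wnt count was 3 higher and 0 lower, with Rspo3, named here after its values were seen and with 13.1% of its exon bases under other genes, as the added call. No TGF-beta and BMP pathway gene of 32 was called, also adjusted over the list alone (camera adjusted p = 0.24, and 0.0335, on the higher side, without control replicate 3); Inhba was at 2.43 ± 0.0588 and 1.7 ± 0.245 FPKM and Tgfb1 at 7.52 ± 0.975 and 9.2 ± 1.08. The partners of LSD1 in its complexes had 0 of 21 called (camera adjusted p = 0.841), with Sfmbt1 at 2.1 ± 0.088 and 2.6 ± 0.113 FPKM and Rcor1 at 8.43 ± 0.243 and 9.57 ± 0.567. Enzymes of H3K4 methylation had 0 of 20 called (camera adjusted p = 0.868), with Smyd1 at 105 ± 6.91 and 124 ± 1.73 FPKM and Dpy30 at 74.1 ± 8.73 and 61.2 ± 1.34 (SD, n = 3 each). Immediate early and heat shock genes had 0 of 28 called (camera adjusted p = 0.444), with Atf4 at 65.9 ± 3.11 and 57.5 ± 1.21 FPKM and Ddit3, with 10.9% of its exon bases under other genes, at 8.19 ± 1.51 and 6.44 ± 0.32. For these 3 lists the counts adjusted over the list alone were also 0. Of 32 Hox genes 1 was tested, Hoxb4, at 0.823 ± 0.0673 and 0.612 ± 0.1 FPKM, and it did not pass. The 5 sex-linked genes were not called, also adjusted over the list alone (camera adjusted p = 0.465).

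In all, 5 lists were called by camera at its preset correlation, 2 higher and 3 lower, and 0 with an estimated correlation. By the directional fry test 1 list was called, the neuronal one, and none of these 5 (adjusted p = 0.0897 to 0.694). The mixed fry test asks whether members change in either direction. It passed for nuclear oxidative phosphorylation (adjusted p = 0.00592), germline (0.0024) and immune genes (0.0417), but not for glycolysis (0.0809) or fatty acid oxidation (0.0996). It also passed for lists that camera did not call, such as cardiac transcription factors and skeletal muscle genes (6.15e-05 each). Of the 58 genes named above by the rule that passed the test, 29 stayed called in each of the 6 fits that left out a library. The calls of Isg15, Tnni2, Fbln5, Psd, Aldoc, Fabp4, Tnnt1, Syt11, Gadd45g, Perp, Irx6, Irx5, Foxc1, Fhl2, Hrc, Kcnj8, Cacna1h, Kcnj3, Nppa, Nppb, Dkk3, Tcf7, Fzd1, Krt8, Epcam, Eno3, Slc2a3 and Bnip3 were each lost in at least 1 of them, with no change of direction. Of these, Fbln5, Tcf7 and Epcam were called in 0 of the 6 fits. Psd, Fabp4, Gadd45g, Irx5, Foxc1, Fhl2, Hrc, Cacna1h, Kcnj3, Fzd1 and Bnip3 were each called in 1. With the sex score as covariate 30 of the 58 stayed called.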

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

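The voom fit and the autosomal fit were chosen after the data were seen, and the other settings before. Kdm1a stayed lower and Cend1 higher, past the threshold, under every setting run, with log2 changes of -1.35 to -1.15 and 1.47 to 1.74. The main counts were 270 higher and 66 lower genes and 5 lists, and the causes of the shifts below were not tested. With no filter on low values 110 genes were higher and 12 lower, in 25956 genes tested. A mean of at least 5 FPKM gave 132 higher genes and 3 lists, in 7420 genes tested. Rescaling to TPM gave 40 lower genes and 90.2% of calls higher, against 80.4%, and library weights gave 112 lower genes and 10 lists. The sex covariate gave 93 higher and 23 lower genes and 9 lists. Voom on recovered reads called 409 higher and 102 lower genes, 301 of them among the main 336. An adjusted p under 0.01 left 80 and 8, and a 1.5-fold minimum left 31 lower genes. Among the genes named, most calls were lost at an adjusted p under 0.01 (33), without the filter (32) and with the sex covariate (28), and none changed direction. An estimated correlation called 0 lists. The directional fry test called 1, the neuronal list, and none of the 5 that camera called (adjusted p = 0.0897 to 0.694). Leaving out 1 library gave 109 to 281 higher genes, 23 to 113 lower genes and 3 to 15 lists, and the group with a lost library then has 2.

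For the neuronal list the camera adjusted p was 0.0259 with the sex covariate, 0.0438 by voom and 0.0452 on autosomes, and fry gave 0.0116. The camera value was 0.14 without the filter, 0.145 at a mean of at least 5 FPKM and 0.105 after rescaling to TPM. When a library was left out it was 0.0261 to 0.0884. The adjusted p of this list ranged from 0.0116 to 0.786 over all settings run. The G2 and M list had 0.0314 without the filter, 0.00127 with library weights, 0.0233 with the replicate block, and 2.11e-07 to 0.682 when a library was left out. The G1 and S list had 0.0324 with library weights and 0.00441 to 0.867 when a library was left out. Sarcomere genes ranged from 0.00137 to 0.965 in the same way. The cell cycle phase and sarcomere lists each had 0.883 with an estimated correlation, run on all 6 libraries. The mitochondrially encoded list had 0.0392 with the replicate block, on the lower side. Over all settings run, the adjusted p ranged from 0.0105 to 0.93 for the mitochondrially encoded list, 0.00526 to 0.883 for wall signalling, 0.0227 to 0.851 for neural crest, 0.0195 to 0.965 for epicardial, 0.00258 to 0.964 for endothelial, 0.00449 to 0.883 for hypoxia, 0.0242 to 0.883 for calcium handling, 0.0324 to 0.97 for erythroid and 0.0335 to 0.883 for TGF-beta and BMP genes. The called lists ranged from 7.66e-13 to 0.786 (nuclear oxidative phosphorylation), 1.57e-08 to 0.883 (glycolysis), 3.91e-05 to 0.883 (fatty acid oxidation), 1.9e-05 to 0.843 (immune) and 0.000246 to 0.786 (germline). Cushion mesenchyme genes turned to the higher side without control replicate 3 (adjusted p = 0.0385, in a range up to 0.93). The same-numbered samples deviated together with correlations of 0.00, 0.14 and 0.16, so the numbers were not taken to pair them, and not every sample correlated best with its own number; the replicate block gave 284 calls, 233 of them shared. The comparison of count tools that was planned for a table with counts was not run, since the table holds FPKM. Depth limits genes near 0.155 to 0.169 FPKM, where 3 reads stand in 1 kb.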

Other observations

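Chosen after the result was seen were the counts of other splits, the comparison of interferon-stimulated genes with immune markers, the overlap of neuronal genes with neighbours, the further comparison of neuronal transcripts described as such below, the Fisher tests of X-linked genes, the calls counted without a library for the single-library and sex explanations, and the interferon, epithelial and abundant neuronal lists with the genes named from them; the other tests here were written before. Genes of the interferon response rose in the knockout. Of 51 tested interferon-stimulated genes 21 rose and 0 fell, with a median log2 change of 0.59. Bst2, which holds budding virus at the cell surface, rose from 21.1 ± 2.71 to 48.8 ± 5.39 FPKM, the antiviral gene Ifit1 from 0.164 ± 0.109 to 1.85 ± 0.824, the transcription factor gene Irf7 from 0.505 ± 0.273 to 1.56 ± 0.147 and Ifitm3 from 23 ± 4.39 to 44.7 ± 5.82 (SD, n = 3 each). The list had camera adjusted p = 3.63e-27, adjusted p = 0.343 with an estimated correlation and 0.0288 by fry, all on a list picked because its genes were called. The count of 21 fell to 4 without knockout replicate 3, 6 without knockout replicate 2, 12 without knockout replicate 1, and 9, 7 and 16 without control replicates 1, 2 and 3, and it was 4 with the sex covariate.

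Genes of epithelial adhesion and keratins rose as well, 11 of 27 tested with 0 lower and a median log2 change of 0.35. Krt20 went from 2.24 ± 0.287 to 5.65 ± 0.198 FPKM, the tight junction gene Tjp3 from 0.386 ± 0.181 to 1.97 ± 0.242, F11r from 19.6 ± 0.916 to 28.2 ± 1.48 and Cd24a from 42.4 ± 0.957 to 62.8 ± 4.38 (SD, n = 3 each). Krt19 stood at 64.5 ± 19.4 and 58.5 ± 2.77 FPKM, and the epithelial cadherin gene Cdh1 at 0.0505 ± 0.0477 and 0.0422 ± 0.0419. The list had camera adjusted p = 1.94e-07, adjusted p = 0.27 with an estimated correlation and 0.0169 by fry, on a list chosen from the called genes. The count of 11 fell to 5, 7 and 9 without control replicates 1, 2 and 3, to 6, 4 and 5 without knockout replicates 1, 2 and 3, and to 2 with the sex covariate. The heart itself expresses some of these genes in its epicardium, and Krt8 and Krt19 are also in the epicardial list.

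The interferon pattern may have come from more immune cells in the knockout dissections, from a single library, or from a response that differed with genotype. For the first, the median change of the 25 immune markers lay -0.47 from that of the interferon-stimulated genes (bootstrap SE 0.09, genes taken as independent). This decides nothing, because the interferon list was picked for its called genes, which raises its median. More immune cells therefore stay open. For a single knockout library, the lowest knockout library lay 0.37 above the highest control library in the mean log2 level of the list, which decides nothing because called genes had such libraries by selection. Called without each knockout library in turn were 4 of the 21 genes, Bst2, Ifit2, Oas1a and Parp12, which argues against a single knockout library for these 4 and leaves it open for the other 17. An altered state of resident immune cells, strain background, an infection, a difference between litters, which were not recorded and are not separable from genotype here, and an effect of genotype all stay open and untested.

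The neuronal rise may reflect neuronal cells in the knockout dissections, reads of neighbouring genes, or expression in the heart cells. For the first, a comparison written before the values of the abundant transcripts were seen, on a list written after the called genes were seen, did not decide: 10 abundant neuronal transcripts rose by 0.255 FPKM on average against 7.75 FPKM for the 5 called genes, a difference of -7.5 with SE 5.58, a wide error because Uchl1 dominates the called genes. A further comparison, chosen after that one was undecided, set the same mean against the smallest rise of a called gene, Scg5 at 1.06 FPKM, and gave -0.81 (SE 0.198). It rests on the 7 transcripts below the 0.5 FPKM filter (mean rise 0.0217, SE 0.0392, none above 0.388 FPKM in the knockout mean), while the 3 past it, Tubb3 at 2.31 ± 0.787 and 2.28 ± 0.597, Nefl (32.8% of its exon bases lie under other genes) at 0.803 ± 0.247 and 1.25 ± 0.233 and Gap43 at 27.6 ± 1.02 and 29.6 ± 4.12 FPKM (SD, n = 3 each), rose by 0.798 on average (SE 0.604), so neuronal cells stay open. Exon overlap above 5% was found for 2 of the 5 genes, Gng3 and Uchl1, and stays open for these 2. Kif1a, Scg5 and Syt11 had an overlap of 0%, so overlapping annotated exons cannot account for them. Reads of neighbours outside annotated exons were not measured. Expression in heart cells is a hypothesis not tested here.

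The uneven sex of the libraries could have produced calls; without knockout replicate 3, the library with Xist and no Y-linked reads, the median called gene kept 1.01 of its log2 change, which decides nothing because the genes were chosen for the change. That fit called 123 higher and 27 lower genes, 136 of them among the 336, which argues against the sex of that library for these 136; the other 200 are no evidence for it, since 153 were shared without knockout replicate 1, 127 without knockout replicate 2 and 153, 170 and 243 without control replicates 1, 2 and 3, but for them it was not excluded. Of the 270 higher genes 20 were X-linked, against 511 of 14149 tested (two-sided Fisher's exact test p = 0.00244, genes taken as independent). In knockout replicate 3 these 20 lay at a median of -0.04 on the log2 scale from the other knockout libraries, a closeness that selection favours, while without that library 9 of 123 higher genes were X-linked, against 506 of 14130 tested (two-sided Fisher's exact test p = 0.0436), which argues against its sex as the source of the share in these 123, by a p near the threshold, and leaves the other higher genes open. The Xist of knockout replicate 1, 9.19% of the level in replicate 3, beside Y-linked levels at 104% of the other libraries, stays open, since a trace of another sample and a mixed sample were not tested.

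Of the 10 splits of the 6 libraries into 3 and 3, the real one called 336 genes and the highest other called 1, so 1 split reached the real count. For gene lists the real split called 5 and the highest other 16, and 8 of the 10 splits, the real one included, called at least 5. With 10 splits no share under 0.05 can be reached. Some other splits called more lists than the real one, so a list call by camera at its preset correlation is not particular to genotype. Whether a structure of the samples caused those calls was not tested.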
